A study of Mus musculus with 16 samples.

How the data were processed

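ATAC-seq, in which a transposase cuts and tags open DNA, was performed on 50000 neural stem and progenitor cells per sample together with 50000 Drosophila melanogaster S2 cells as a spike-in, and libraries were amplified for 10 cycles and sequenced on a NextSeq 2000, per the labels' protocols. The cells had been isolated from dorsal telencephalon at embryonic day 12.5 and cultured as neurospheres, per the labels' protocols. The labels give 4 groups of 4 samples: Kat6b knockout and wild type on C57BL/6, and Tg(Kat6b) and wild type on FVB x BALB/c. Per the series design text each sample is a separate embryo, so the p-values measure the spread between embryos and their cultures within a group. The labels give no sex, litter or preparation date.

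The authors deposited whole-number counts of reads per region for 3 classes of region in each sample: promoters of 2001 bp, regions named for H3K4me1 and H3K27ac enrichment, and windows of 1001 bp downstream of transcription end sites. Reads were counted with featureCounts on the genome build mm39, per the submitters' processing notes, which give no version or settings. The aligner, read filters and the treatment of spike-in reads are not given in the sources used here. The 48 deposited count files of single samples held the same values as the columns of the series tables, and all 16 columns of each table were mapped to samples by name. Promoters and gene ends carry numeric gene IDs, of which 20091 of 20113 were matched to symbols in a RefSeq table for GRCm38.p6. That table was used only for names, chromosomes and the order of genes, and none of its coordinates is printed. Enhancer regions are named in the deposited tables by an mm9 chromosome and start, which are printed as given, and are not assigned to genes. Counts in windows that overlap, as for Ap3m1 and Adk, and in copies of multigene families can hold the same reads or reads of a paralog, and such genes are given as uncertain.

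Total counts per library were 1384643 to 5015408 at promoters, 894485 to 2552692 in enhancer regions and 198347 to 489743 at gene ends. The median tested region held 49 to 158 counts per library at promoters, 30 to 85 in enhancer regions and 8 to 17 at gene ends, so gene ends allow only large changes to be seen. The enhancer regions at 98504851 on chromosome 2, 39982828 on chromosome 17, 3110474 on chromosome 12 and 35112944 on chromosome 9 together took 9.80% to 17.0% of enhancer-region counts and stayed in the tables. Between all 24 pairs of replicates of a class the counts differed by more than sampling noise (chi-square per degree of freedom at least 1.05 at promoters, 1.04 in enhancer regions and 1.02 at gene ends, the highest p being 0.0269), so no library was taken to be deposited more than once. Confidence intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The interval of a count is an exact 95% Poisson interval, and a group at 0 was set to a floor of 3 counts per library.

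Within each class, regions on chromosome Y and at Xist and Tsix were left out (17 promoters, 13 enhancer regions and 17 gene ends), low counts were filtered with filterByExpr, and libraries were scaled with TMM factors. This left 20008 promoters, 16782 enhancer regions and 15186 gene ends. The 16 libraries entered a single edgeR quasi-likelihood fit per class with robust dispersion estimates and a coefficient per group (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Contrasts were KO against WT, Tg against WT, the difference of these effects, and WT FVB x BALB/c against WT C57BL/6, with Benjamini-Hochberg adjustment over all regions tested and a threshold of 0.05. Standard errors of log2 changes were derived from the quasi-likelihood statistic. CPM are TMM-normalised group means with SD over 4 libraries. The biological coefficient of variation was 0.0378 at promoters, 0.0473 in enhancer regions and 0.0777 at gene ends.

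Total promoter and enhancer-region counts were set against total gene-end counts of the same library, and the log2 ratios were compared with a two-sided exact permutation test, whose smallest possible p is 0.0286. The 18 gene lists at promoters were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. The lists were the KAT6 complex, other histone acetyltransferases and deacetylases, neural stem and progenitor cell genes, neurogenesis and neuronal genes, glial genes, ventral telencephalon and interneuron genes, the SOX family, HOX genes, clustered protocadherins, cell cycle and DNA replication genes, cell cycle inhibitors, synapse and autism-associated genes, microglia and leukocyte genes, endothelial genes, erythroid genes, mesenchymal and meningeal genes, pluripotency and germline genes, and general housekeeping genes. Of these, 4 neural stem, 6 SOX, 2 glial, 1 neurogenesis and 1 synapse genes stand in more than 1 list. The designs, lists and most alternative settings were fixed before the data were examined.

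Genes named in the text were chosen by a fixed rule. Kat6b came first, then the 10 largest rises and 10 largest falls at autosomal promoters that passed, had no overlap between the 4 values of each group, had at least median abundance and carried an established symbol. The same rule gave 5 and 5 enhancer regions, 3 and 3 gene ends, at most 4 members of each list by smallest p, and the 5 promoters with the smallest p for the difference of effects and for the backgrounds. Regions within 1 Mb of Kat6b were described as a locus. Klhl13, Wdr44 and the Y-linked genes were named after their values had been seen.

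The fits were tested on simulated counts with 200 changed regions among those of each class. Recovery is given over the changed regions that passed the filter after simulation. At promoters 70.1%, 88.1% and 95.5% of 1.5-fold, 2-fold and 3-fold changes were recovered in the KO design (19921 regions) and 68.7%, 89.6% and 100% in the Tg design (19924 regions). In enhancer regions 72.7%, 86.4% and 100% were recovered for KO (16495 regions) and 58.5%, 90.9% and 89.2% for Tg (16468 regions). At gene ends 9.52%, 44.4% and 82.3% were recovered for KO (14105 regions) and 13.3%, 62.5% and 90.0% for Tg (14083 regions). With camera, 0 of 100 random lists had an unadjusted p under 0.05 in the KO and in the Tg design. The simulated regions were drawn independently of one another, so this cannot show how camera behaves where promoters change together. False calls made up 2.30% (gene ends in KO) to 6.63% (promoters in KO) of the simulated calls. The simulated rises and falls were balanced and did not depend on abundance. In the real Tg comparison 57.3% of promoters passed and direction followed abundance, so the simulated recovery cannot be carried over to it.

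The alternatives were RLE size factors, total library size alone, the TMM factors and library sizes of another class, offsets that follow abundance in each library (loess, span 0.3), no filter, autosomal regions only, fits on the compared groups only, limma voom with quality weights, DESeq2 1.42.0, a threshold of 0.01, the replicate number as a block, and leaving out each library in turn. For lists they were an estimated correlation, fry, gene-end factors, the block and the offsets. DESeq2 gave no adjusted p for regions removed by its independent filtering, from 0 promoters in the Tg comparison to 12365 of 15186 gene ends in the Tg comparison, and these were left out of its counts. Single values of 3 members of the gene lists are not reported here, and the tests of the lists include these genes.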

Results

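Chromatin accessibility was profiled in 16 ATAC-seq libraries of neural stem and progenitor cells, grown as neurospheres from the dorsal telencephalon, the embryonic source of the neocortex. The comparisons ask what loss and gain of KAT6B do to open chromatin. KAT6B is a histone acetyltransferase that works in a complex with BRPF, ING and MEAF6 subunits. Loss was studied in 4 homozygous Kat6b knockout (KO) embryos against 4 wild-type (WT) embryos on C57BL/6. Gain was studied in 4 embryos carrying the Tg(Kat6b) transgene (Tg) against 4 WT embryos on an FVB x BALB/c hybrid background, so the KO and Tg comparisons share no library. Reads had been counted over 20113 promoters, 20792 regions carrying the enhancer-associated marks H3K4me1 and H3K27ac (enhancer regions below), and 20113 windows downstream of transcription end sites (gene ends). Total counts over the 3 classes ran from 2477475 to 8039884 per library, with means of 4200919 in WT C57BL/6, 5428300 in KO, 3932429 in WT FVB x BALB/c and 7305310 in Tg. Enhancer-region counts on chromosome Y stood at 43.0 ± 4.13 CPM (counts scaled to library size; SD, n = 4) in WT C57BL/6, 38.4 ± 3.45 in KO and 54.1 ± 5.79 in WT FVB x BALB/c, but at 0.967, 0.458, 0.787 and 9.01 in Tg libraries 1 to 4. In the Tg comparison the Y signal therefore separated the groups as the genotype did.

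The Kat6b locus was examined first, since it checks the KO and Tg labels. Reads here also follow the number of DNA copies, which a transgene would raise and a deletion would lower. Copies were not counted, so the values at this locus are not read as changes of accessibility. The Kat6b promoter stood at 3175 ± 309 CPM (SD, n = 4) in Tg and at 230 ± 5.39 in WT FVB x BALB/c, a 13.8-fold difference (log2 change 3.79, SE 0.05, edgeR adjusted p = 5.9e-128). Tg library 4 had the lowest transgenic value, 2744, against 3232 to 3477 in Tg libraries 1 to 3. In KO the same promoter was not called different from WT (298 ± 2.12 against 273 ± 22.9; log2 change 0.13, SE 0.05, edgeR adjusted p = 0.167). Inside the surrounding chromosome 14 interval, however, the 5015 bp enhancer region that starts at 22366417 (mm9) had 0 counts in all 4 KO libraries and 402 in the 4 WT libraries. Its WT level was 68.4 ± 4.69 CPM, and with a floor of 3 counts per KO library it was at least 41.8-fold lower in KO. In Tg this region rose from 84.7 to 586 CPM (log2 change 2.80, edgeR adjusted p = 7.6e-90). A neighbouring 1161 bp region at 22321389 rose from 88.5 to 1442 in Tg (log2 change 4.02, edgeR adjusted p = 6.1e-115) and was not called in KO (log2 change -0.13, edgeR adjusted p = 0.335). The deposited tables do not assign these regions to genes. At gene ends, Kat6b rose by 3.08 and the adjacent phosphatase gene Dupd1 by 3.54 on the log2 scale in Tg (edgeR adjusted p = 1.3e-54 and 4.4e-71). The Dupd1 promoter rose by 1.67 (edgeR adjusted p = 6.4e-17), while the next phosphatase gene, Dusp13, was not called at its promoter (0.03, edgeR adjusted p = 0.879). Beyond Dusp13 the promoters of Samd8 (0.35) and Vdac2 (0.30) rose slightly. On the other side of Kat6b those of Ap3m1 and Adk, whose windows overlap and share reads, rose by 0.40 each. These rises did not taper with distance: the farther promoters of Camk2g (0.52) and Ppp3cb (0.55) rose more, while those of Plau (0.03) and Zfp503 (0.04) were not called.

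**Figure D1:**
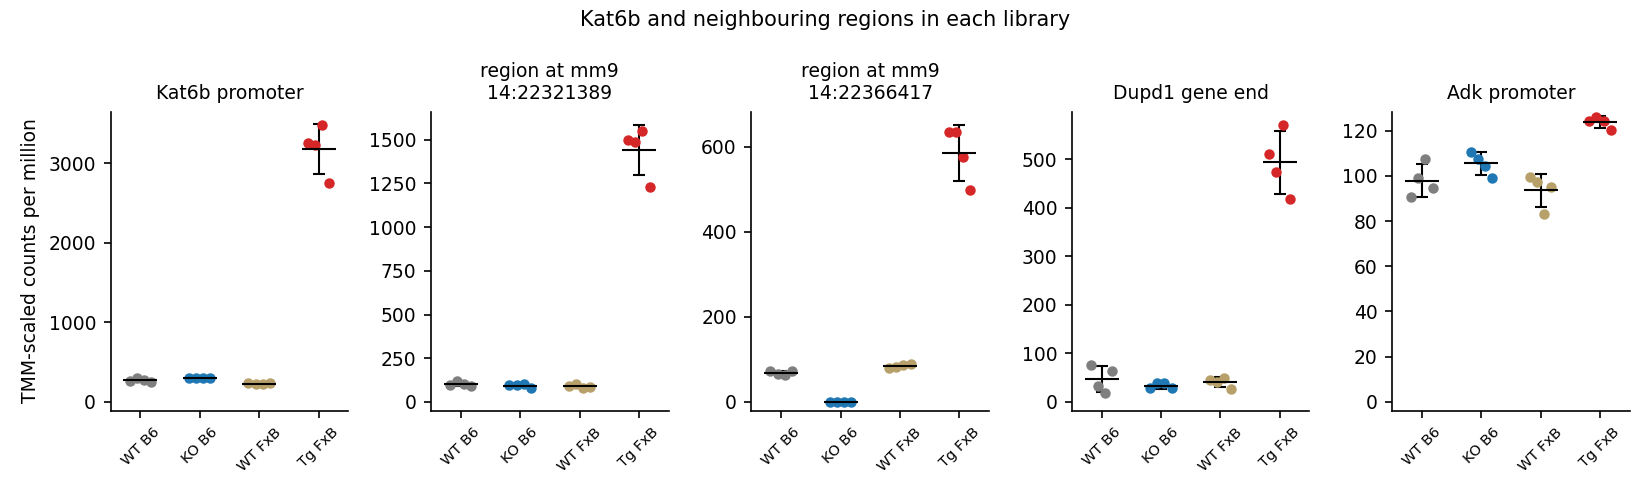
CPM at regions of the Kat6b locus and at the neighbouring genes Dupd1 and Adk in the 4 groups, with points for libraries, horizontal lines for group means and bars for SD (each panel has its own axis). The KO libraries lie at 0 counts at the region starting at 22366417, and the 4 Tg libraries at the Kat6b promoter lie between 2744 and 3477, above all WT libraries.

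Loss of Kat6b was accompanied by modest changes at a small share of promoters. The largest rise among well-covered autosomal promoters was at Oacyl, which went from 22.6 ± 4.65 to 45.7 ± 5.79 CPM (SD, n = 4; log2 change 0.98, SE 0.12, edgeR adjusted p = 1.5e-11). Fez1, an adaptor in axon outgrowth, rose from 46.2 to 78.5 (log2 change 0.76, SE 0.09, edgeR adjusted p = 2.5e-12), and the non-muscle myosin Myh14 from 99.7 to 147 (0.55, SE 0.07, 1.9e-11). Garnl3 fell from 140 to 90.1 (log2 change -0.63, SE 0.07, edgeR adjusted p = 1.1e-13), the potassium channel gene Kcna6 from 49.8 to 30.0 (-0.71, SE 0.11, 8.6e-08), and Id1, an inhibitor of basic helix-loop-helix factors, from 121 to 84.5 (-0.51, SE 0.07, 1.4e-08). Of 20008 promoters tested, 798 passed, 418 higher and 380 lower, with a median absolute log2 change of 0.36, and 31 of them changed at least 2-fold. The balance turned to 294 higher and 425 lower with library totals and to 269 and 430 with offsets that follow abundance. The other leading rises were at Dnajc5b (0.67), the BMP antagonist Vwc2 (0.64), Optc and Trim16 (0.56 each), the guanine nucleotide exchange factor Arhgef2 (0.54), the protease Adamts4 (0.53) and the selenium carrier Selenop (0.53). The other leading falls were at Akr1e1 (-0.68), the neuronal adhesion gene Cadm3 (-0.58), Baiap2l1 and Anxa2 (-0.57 each), the acetylcholinesterase gene Ache and Nkain4 (-0.53 each), and the mesenchymal homeobox gene Prrx1 (-0.51). Most leading promoters also differed the same way between WT FVB x BALB/c and WT C57BL/6, such as Oacyl (1.01) and Id1 (-1.18). Arhgef2 (-1.42) and Akr1e1 (1.87) differed the other way. Of the 418 rises, 98 were also higher and 57 lower in WT FVB x BALB/c (29.2 and 49.1 from independent lists). Of the 380 falls, 130 were also lower and 30 higher (44.7 and 26.5). Sharing the WT C57BL/6 libraries by itself makes such matches rise. Chromosome X stood apart: 110 of its 119 changed promoters were lower, and 103 of the lower ones lay among the 142 most proximal X genes. On autosomes 409 promoters were higher and 270 lower. All 4 values of one group lay above all 4 of the other at 10.0% of promoters, where chance gives 2.86%. Scaling to the proximal X counts, chosen after the data were seen, moved the median change over all promoters from -0.01 to 0.75, which by itself turns falls of this size upward, Garnl3 to 0.13 for example. With every library thinned to the smallest total, 67 promoters passed.

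The fixed gene lists moved little in KO. Of 24 neural stem and progenitor genes 3 rose, none fell and 21 did not pass, with the same count adjusted over the list alone. These were the Notch effector Hes1 (0.32, edgeR adjusted p = 3.3e-06), the cortical patterning gene Nr2f1 (0.40, 3.6e-05) and Dmrta2 (0.37, 6.0e-05). The list as a whole shifted upward (median log2 change 0.07, camera adjusted p = 0.0106), but not with an estimated correlation (adjusted p = 0.116 with an estimated correlation). Of 28 cell cycle and DNA replication genes 2 rose, Ccne2 (0.26) and Cdk1 (0.27), as also when adjusted over the list alone. That list also shifted upward (median 0.09, camera adjusted p = 0.00806), a call lost in the same way (adjusted p = 0.197 with an estimated correlation). With offsets that follow abundance, used for lists after the data were seen, neither list passed (camera adjusted p = 0.214 and 0.307), and the HOX list did (median 0.15, 0.00807, and 0.0255 with an estimated correlation). Of 24 neurogenesis genes 2 fell, the synaptic vesicle gene Syt1 (-0.43) and the neuronal tubulin gene Tubb3 (-0.38), against 3 lower and 1 higher adjusted over the list alone. The list itself did not pass (median -0.10, camera adjusted p = 0.433). Single members passed in several other lists. The acetyltransferase gene Crebbp rose (0.30) in the list of 18 other acetyltransferases and deacetylases (2 higher adjusted over the list alone), and the chromatin genes Arid1b (0.26) and Chd8 (0.22) rose among 30 synapse and autism-associated genes (4 higher and 2 lower adjusted over the list alone). Dlx5 fell (-0.43) among 15 ventral telencephalon genes (1 higher and 2 lower adjusted over the list alone). Adjusted over the list alone, the same single calls held for Cdkn1a (-0.43) among 13 cell cycle inhibitors, Pcdha11 (-0.96) among 58 clustered protocadherins, and Gusb (-0.38) among 20 housekeeping genes. None of the 8 KAT6 complex, 16 glial, 19 SOX family, 39 HOX or 12 pluripotency promoters passed, over all promoters or adjusted over the list alone (camera adjusted p = 0.542, 0.750, 0.433, 0.433 and 0.470). At an unadjusted edgeR p under 0.05 these lists held 1, 2, 4, 5 and 2 members, and DESeq2 and limma called 0. Of the markers of other cell types, Cd68 rose (0.56) among 12 microglia and leukocyte genes, Erg rose (0.46) and Cdh5 fell (-0.60) among 10 endothelial genes, and the proximal X gene Gata1 fell (-0.57) among 12 erythroid genes. Tbx18 rose (0.28) beside the fall of Prrx1 among 13 mesenchymal and meningeal genes (2 higher and 2 lower adjusted over the list alone), and none of these marker lists passed.

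A larger share of enhancer regions than of promoters passed in KO, 21.4% against 3.99%. The enhancer region at 31123589 on chromosome 9 (mm9, 1716 bp) rose from 12.3 to 49.6 CPM (log2 change 1.98, edgeR adjusted p = 6.1e-22), and that at 16731579 on chromosome 11 (2185 bp) from 54.6 to 185 (1.76, 8.1e-43). The region at 123299911 on chromosome 2 (1768 bp) fell from 79.8 to 19.6 (edgeR adjusted p = 3.9e-32), and that at 62968123 on chromosome 13 (3427 bp) from 162 to 49.0 (-1.72, 1.9e-41). Of 16782 enhancer regions tested, 3597 passed, 2058 higher and 1539 lower (median absolute log2 change 0.47), and groups did not overlap at 21.7% of them (2.86% by chance). With libraries thinned to equal depth 1502 passed, and with the factors of gene ends 2366 were higher and 825 lower. All 5 leading rises and the 4 leading falls outside the Kat6b locus also differed the same way between WT FVB x BALB/c and WT C57BL/6, by 0.97 to 2.46 and by -0.55 to -1.30. Among the 89 KO rises of at least 2-fold, 74 were higher and 0 lower in WT FVB x BALB/c than in WT C57BL/6 (17.3 lower from independent lists). The 79 falls of that size held 56 lower and 5 higher (15.4 and 14.2 from independent lists). Both comparisons use the WT C57BL/6 libraries, which by itself makes such counts rise.

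At gene ends 231 of 15186 windows passed in KO, 102 higher and 129 lower, but 92 of the lower ones lay on X and autosomes had 138 calls, 37 of them lower. The count was 139 without WT C57BL/6 library 4, 117 in a fit of autosomal windows only and 88 after thinning to equal depth, and with library totals 77 were higher and 188 lower. The end of Fndc5, the precursor gene of irisin, rose from 312 to 728 CPM (log2 change 1.24, edgeR adjusted p = 1.2e-18), and those of She and Mynn rose by 1.43 and 1.46. The end of Ankrd55 fell from 117 to 31.5 (-1.84, 2.0e-09), and those of the transducin gene Gnat2 and of Pcdh20 fell by 1.39 and 1.34. Counts over the whole promoter class relative to gene ends did not differ detectably between KO and WT (log2 ratio 0.09 higher, SE 0.05, n = 4, two-sided exact permutation p = 0.171), nor did those of enhancer regions (0.08, SE 0.03, exact permutation p = 0.0857). These depended on single libraries: without WT C57BL/6 library 2 the ratios were 0.12 and 0.11 (exact permutation p = 0.0286 for both), and without WT C57BL/6 library 4 they were 0.0510 and 0.0525.

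**Figure D2:**
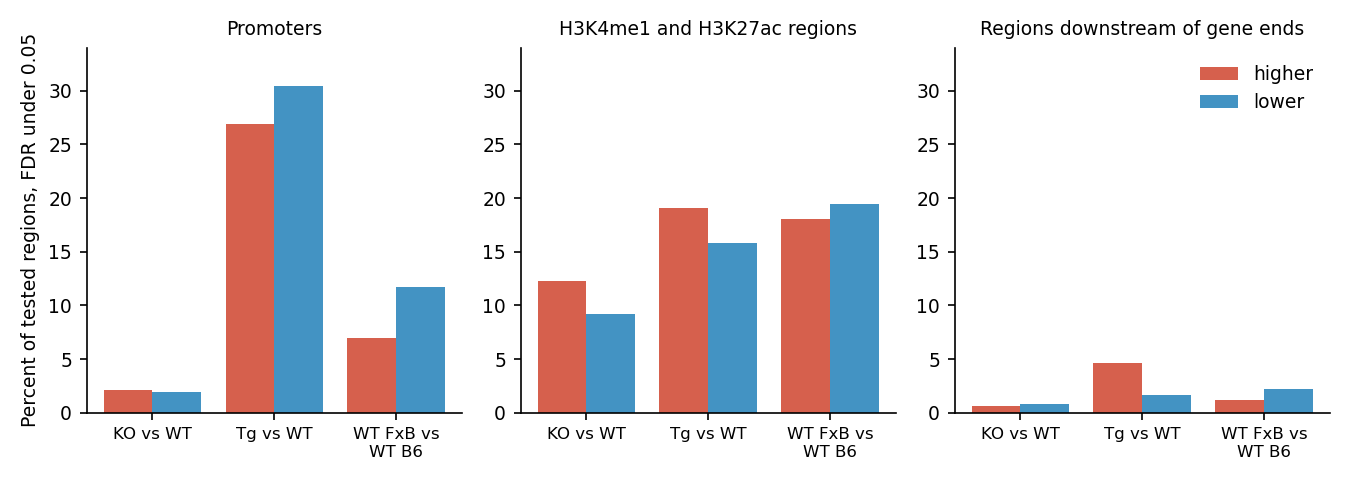
Percentage of tested regions called higher and lower at an adjusted p of 0.05 in KO, in Tg and between the WT backgrounds, for promoters, enhancer regions and gene ends. Promoter calls make up 3.99% of 20008 in KO and 57.3% in Tg, a Tg set with 5377 higher and 6093 lower that becomes 10047 higher and 1290 lower with the factors of gene ends.

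Gain of Kat6b was accompanied by changes at a majority of promoters. Leading rises were at Sox1, a transcription factor of neural progenitors, from 57.6 ± 1.40 to 120 ± 6.80 CPM (SD, n = 4; log2 change 1.06, SE 0.07, edgeR adjusted p = 1.1e-29), and at Polr2a, the gene of the largest RNA polymerase II subunit, from 135 to 257 (0.93, SE 0.06, 1.4e-36). Gad1, which makes the enzyme of GABA synthesis, rose by 0.93, the angiogenic factor gene Vegfa by 0.91, and Zfp608, Phf21a, Fgf11, Sumo2 and Svop by 0.88 to 0.96. Leading falls were at the class Ib histocompatibility gene H2-M3, from 57.1 to 22.2 (log2 change -1.34, SE 0.11, edgeR adjusted p = 2.0e-25), and at Snai2, a repressor in epithelial to mesenchymal transition, from 65.6 to 31.3 (-1.09, SE 0.09, 2.9e-21). Plscr4 (-1.16), Plppr4 (-1.14) and Tmem45a (-1.11) fell too. Falls at Isoc2b (-1.33) and at the zinc finger genes Zfp442, Zfp937, Zfp820 and Zfp970 (-1.17 to -1.28) are uncertain as to the gene, since these have close paralogs that can share reads. In all, 11470 of 20008 promoters passed (57.3%), 5377 higher and 6093 lower, with a median absolute log2 change of 0.47, and groups did not overlap at 45.3% of promoters (2.86% by chance). Of the 902 changes of at least 2-fold, 887 were falls. Direction followed abundance: among the 5002 least accessible promoters 32 rose and 2546 fell (median -0.59), and among the 5002 most accessible 3145 rose and 524 fell (median 0.25). With the factors of gene ends the median change over all promoters moved from -0.10 to 0.32, and 10047 of 11337 calls were higher. With offsets that follow abundance 3619 were higher and 3600 lower, and with libraries thinned to equal depth 4538 passed.

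**Figure D3:**
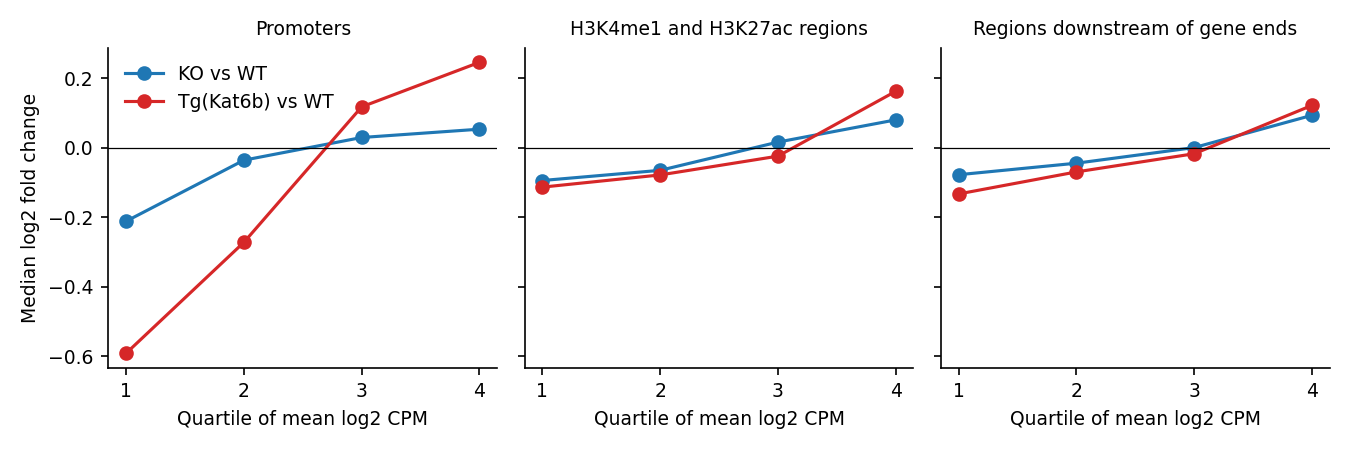
Median log2 change in KO and Tg in 4 groups of regions ordered by mean log2 CPM, for promoters, enhancer regions and gene ends. At promoters the median change in Tg runs from -0.59 in the lowest of 4 abundance groups to 0.25 in the highest, and in KO from -0.21 to 0.05.

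Progenitor and housekeeping promoters gained accessibility in Tg, in libraries whose Y signal lay below that of every WT library. Of 24 neural stem and progenitor genes 14 rose, 3 fell and 7 did not pass (the same adjusted over the list alone), with a median log2 change of 0.31 and camera adjusted p = 3.3e-05 (adjusted p = 0.00286 with an estimated correlation). Beside Sox1 they included Sox2 (0.81) and the Notch effectors Hes5 (0.64) and Hes1 (0.55). The 19 SOX family promoters, 6 of which are also in other lists, had 10 rises and 5 falls, also adjusted over the list alone (median 0.35, camera adjusted p = 1.2e-04, and 0.00392 with an estimated correlation). Sox4 (0.70) and Sox11 (0.66), which act in newborn neurons, were among the rises. Of 13 cell cycle inhibitors 10 rose and 1 fell, also adjusted over the list alone (median 0.32, camera adjusted p = 8.3e-05, and 0.00945 with an estimated correlation), with the stress genes Gadd45b (0.68) and Gadd45g (0.66), the p53 gene Trp53 (0.67) and Cdkn1b (0.52). Of 20 housekeeping genes 14 rose and 1 fell, also adjusted over the list alone (median 0.46, camera adjusted p = 1.2e-08, and 0.00261 with an estimated correlation), for example Hsp90ab1 (0.72) and Gapdh (0.60). In the KAT6 complex Kat6b, its paralog Kat6a (0.53) and Brpf3 (0.51) rose and 5 members did not pass, the same adjusted over the list alone. This list passed (camera adjusted p = 8.3e-14, and 8.0e-05 with an estimated correlation), but not once Kat6b itself was left out (0.0601). Of 18 other acetyltransferases and deacetylases 7 rose, including Ep300 (0.65), Hdac5 (0.63) and Kat7 (0.44), and 1 fell, also adjusted over the list alone (median 0.11, camera adjusted p = 0.0241). That call was lost with an estimated correlation (adjusted p = 0.0911 with an estimated correlation). With offsets that follow abundance, used for lists after the data were seen, the progenitor (median 0.18), SOX (0.16), housekeeping (0.24) and KAT6 complex lists still passed, while cell cycle inhibitors (0.11, camera adjusted p = 0.0895) and the other acetyltransferases and deacetylases (0.17, camera adjusted p = 0.193) did not. With an estimated correlation under these offsets the same 4 lists passed (adjusted p = 0.0209, 0.0228, 0.00939 and 5.3e-05 with an estimated correlation), though the 19 SOX promoters did not when adjusted over 152 gene families (0.193).

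Among HOX and clustered protocadherin promoters falls outnumbered rises in Tg with the TMM factors of promoters. Of 39 HOX promoters 21 fell, also adjusted over the list alone, and 0 rose by edgeR, also at an unadjusted p under 0.05, by DESeq2 or by limma, with Hoxa9 at -0.77 and Hoxb2 at -0.86, and the median was -0.46 (camera adjusted p = 0.00535, and 0.0911 with an estimated correlation), but -0.04 with offsets that follow abundance and -0.05 with the factors of gene ends. Of 58 clustered protocadherins, which diversify neuronal surfaces, 26 fell (25 adjusted over the list alone) and Pcdhgc3 rose (0.36), and the median of -0.48 (camera adjusted p = 0.00409, and 0.144 with an estimated correlation) became 0.04 with the abundance offsets. Neither call held with an estimated correlation. Of 24 neurogenesis genes 12 fell, with Neurod4 at -1.01, the cortical neuron factor Tbr1 at -0.81 and Elavl4 at -0.54, and 3 rose, with Elavl3 at 0.82, also adjusted over the list alone. The list did not pass (median -0.37, which the factors of gene ends turned to 0.04; camera adjusted p = 0.0919). Of 15 ventral telencephalon genes 9 fell, including Isl1 (-1.11) and Lhx8 (-1.06), and 3 rose, including Gad1 (0.93), also adjusted over the list alone (median -0.39, 0.03 with the factors of gene ends, camera adjusted p = 0.277). Glial genes split into 6 rises, among them Sox8 (0.69), Olig1 (0.48) and Olig2 (0.43), and 5 falls, among them Aldh1l1 (-0.69), also adjusted over the list alone. Their median (-0.20) and mean (-0.05) were negative while the test pointed upward (camera adjusted p = 0.491). Cell cycle and replication genes had 7 rises, with Ccne2 (0.34) and Ccnd1 (0.26), and 4 falls (3 adjusted over the list alone), with Cdk6 (-0.32) and Mcm3 (-0.26), which both turned upward with the factors of gene ends (0.10 and 0.17). Their median was 0.06 (camera adjusted p = 0.461), and -0.12 with the abundance offsets, with which the list passed as lower (camera adjusted p = 0.0321, and 0.0707 with an estimated correlation). Synapse and autism-associated genes had 12 rises, with the chromatin regulators Kmt2a (0.62), Pogz (0.57) and Adnp (0.51), and 8 falls, also adjusted over the list alone (median 0.03, mean -0.01, camera adjusted p = 0.154). No list of markers of other cell types passed by camera with the TMM factors of promoters. Falls numbered 4 of 12 microglia and leukocyte genes (2 adjusted over the list alone), 6 of 10 endothelial genes with Flt1 at -0.84, 7 of 12 erythroid genes and 1 rise, and 6 of 13 mesenchymal genes (7, and 1 rise, adjusted over the list alone) with Lum and Col3a1 at -1.02. Of 12 pluripotency genes 4 fell (3 adjusted over the list alone), led by Dppa4 (-1.15). The camera adjusted p of these lists was 0.154, 0.104, 0.110, 0.0601 and 0.137. Their medians, from -0.26 to -0.53, moved to between -0.12 and 0.16 with the factors of gene ends, with which the microglia, endothelial, erythroid and pluripotency lists passed as lower than other promoters (camera adjusted p = 0.0482, 0.04996, 0.0361 and 0.0361). By fry all 5 passed as lower.

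**Figure D4:**
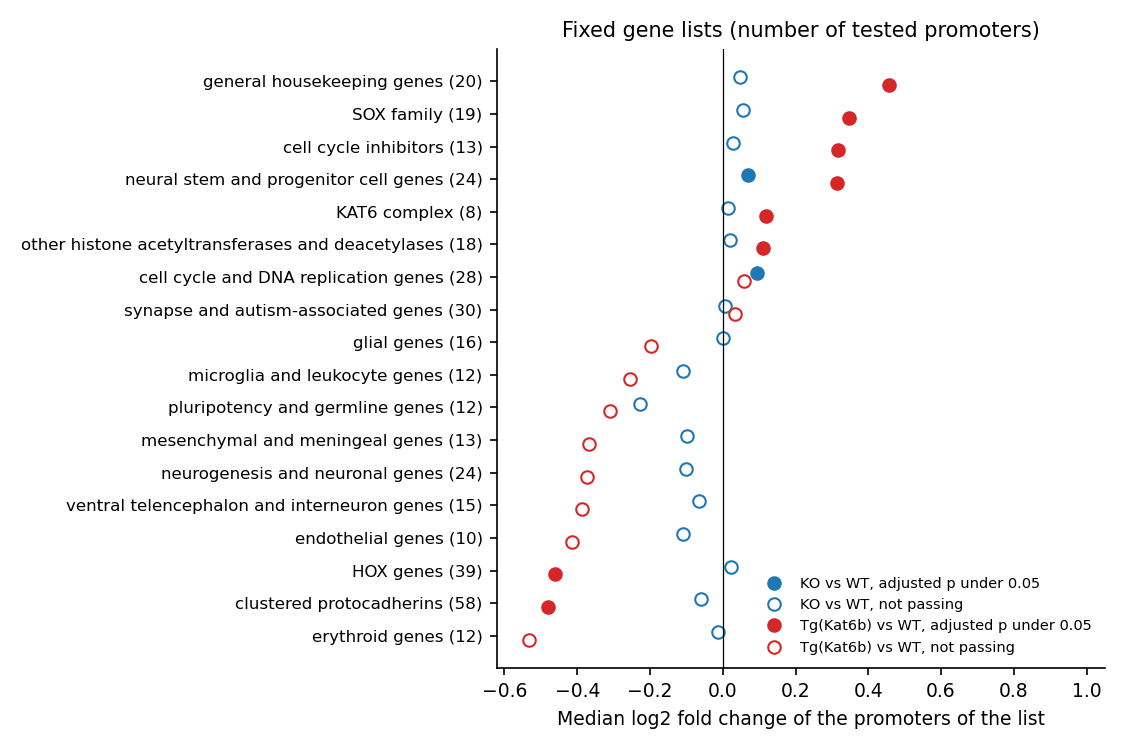
Median log2 change of the promoters of each fixed gene list in KO and in Tg, with filled points where the camera adjusted p is below 0.05 and open points elsewhere. In Tg the housekeeping list lies at 0.46 and the protocadherins at -0.48, the latter turning to 0.04 with offsets that follow abundance.

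Enhancer regions and gene ends also changed in Tg. Outside the Kat6b locus the largest rises were at the enhancer region at 55392758 on chromosome 7 (mm9, 1713 bp), from 15.1 to 50.3 CPM (log2 change 1.73, edgeR adjusted p = 2.6e-20), and at 88282733 on chromosome 12 (1755 bp; 1.58). The region at 154845525 on chromosome 2 (2152 bp) fell from 172 to 43.7 (-1.97, 1.5e-50) and that at 12363374 on chromosome 12 (2101 bp) by 1.86. Of 16782 enhancer regions 5847 passed, 3199 higher and 2648 lower, and groups did not overlap at 29.6% (2.86% by chance). With library totals as the only scaling, 5576 of 7246 calls were lower, with the factors of gene ends 5274 of 6053 were higher, and after thinning to equal depth 3019 passed. At gene ends 952 of 15186 windows passed, 703 higher and 249 lower, led outside the locus by Bpifb3 (2.19), and with falls at Tmem267 (-1.78), Oog1 (-1.28) and Atoh1 (-1.19), a proneural gene. With the factors of promoters 2658 of 2934 gene-end calls were lower, with offsets that follow abundance 287 were higher and 298 lower, and after thinning 549 passed. Promoter counts relative to gene ends were 1.33-fold higher in Tg than in WT (log2 ratio 0.41 higher, SE 0.07, n = 4, two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows, and 0.0571 after adjustment over 4 ratios). Enhancer-region counts relative to gene ends were higher by 0.15 (SE 0.04, exact permutation p = 0.0286, adjusted 0.0571), but by 0.25 with exact permutation p = 0.0857 from median log2 CPM. The exact permutation p was 0.0571 for the promoter ratio without Tg library 1, 2 or 3 and for the enhancer ratio without any 1 Tg library.

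Gain and loss were compared directly through the difference of their effects. Kat6b itself, where the number of DNA copies may differ, had the smallest p (KO change minus Tg change -3.65, edgeR adjusted p = 6.0e-98). Zfp970 (1.26), Isoc2b (1.63), Zfp960 (1.13) and Zfp937 (1.18) followed, all lower in Tg, paralogous as above, and of these only Isoc2b passed in KO (0.30). The effects differed at 5926 promoters, 2527 with the higher value in KO and 3399 in Tg, a balance of 2482 and 2024 with offsets that follow abundance and of 575 and 7024 with the factors of gene ends. They also differed at 4708 enhancer regions, and at gene ends 84 were higher in KO and 320 in Tg. Across promoters, which are not independent replicates, the 2 sets of log2 changes correlated positively (Pearson r = 0.38, Spearman rho = 0.37), but with r = 0.125 under offsets that follow abundance. Across enhancer regions r was 0.06 and across gene ends 0.11. Promoters lower in both comparisons numbered 224 (116 from independent lists) and those higher in both 187 (112). Of the 142 proximal X promoters, 103 were lower in KO and 126 in Tg. A good part of the shared falls therefore lay there, where counts were uneven in every library. Opposite calls numbered 51 lower in KO and higher in Tg (102 from independent lists), such as Garnl3, Anxa2, Ache and Id1, which rose in Tg by 0.24 to 0.50, and 87 higher in KO and lower in Tg (127), such as Dnajc5b (-0.69), Vwc2 (-0.41) and Selenop (-0.88). Enhancer regions higher in both numbered 691 (392 from independent lists), lower in both 342 (243), higher in KO and lower in Tg 467 (325), and lower in KO and higher in Tg 250 (293).

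The WT libraries of the 2 backgrounds differed at 3749 promoters, 1397 higher and 2352 lower in FVB x BALB/c, and at 6288 enhancer regions, 3025 higher and 3263 lower. At promoters the factors of gene ends gave 421 higher and 5773 lower and offsets that follow abundance 1592 and 1740, and in enhancer regions the former gave 1699 and 4915. Akr1e1 stood at 96.2 CPM in FVB x BALB/c and 26.3 in C57BL/6 (log2 difference 1.87, edgeR adjusted p = 2.9e-44). Tmem132c was lower by 2.29 on the log2 scale in FVB x BALB/c. Ccl27b (45.1 to 4.45), Ccl21b (52.6 to 7.81) and Trim12a (37.3 to 2.20) were also lower there, at loci of near-identical gene copies whose reads and copy numbers can differ between strains. This comparison also carries the mapping of FVB and BALB/c reads to a C57BL/6 reference and any separate handling of the lines. It bounds what a comparison across backgrounds can show. Groups did not overlap at 18.7% of promoters and 32.3% of enhancer regions (2.86% by chance).

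Counts along chromosome X were uneven in every library. Gene ends from the start of X through Klhl13 had on average 10.4 times the mean count of gene ends on the rest of X, with 6.21 to 15.1 times in single libraries. Between adjacent genes the total over the 16 libraries dropped from 1337 at the Klhl13 end to 94 at the Wdr44 end. In KO these proximal gene ends had a median log2 change of -0.63 against 0.04 on the rest of X, and in Tg -0.43 against 0.56. The rise on the rest of X in Tg came in libraries whose Y signal lay below that of every WT library, so it cannot be told apart from a difference in sex. The excess of proximal X gene-end counts was divided by autosomal gene-end, promoter and enhancer-region counts and scaled up to an index. This index was 1.71-fold higher in WT C57BL/6 than in KO (2.44 ± 0.376 against 1.43 ± 0.216, SD, n = 4). It was 2.04-fold higher in WT FVB x BALB/c than in Tg (2.82 ± 0.466 against 1.37 ± 0.0925). The exact permutation p was 0.0286 for each. The index is not a multiple of autosomal counts. In WT C57BL/6 library 1, for example, an excess of 10005 counts against 4273068 autosomal counts gave an index of 2.34.

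**Figure D5:**
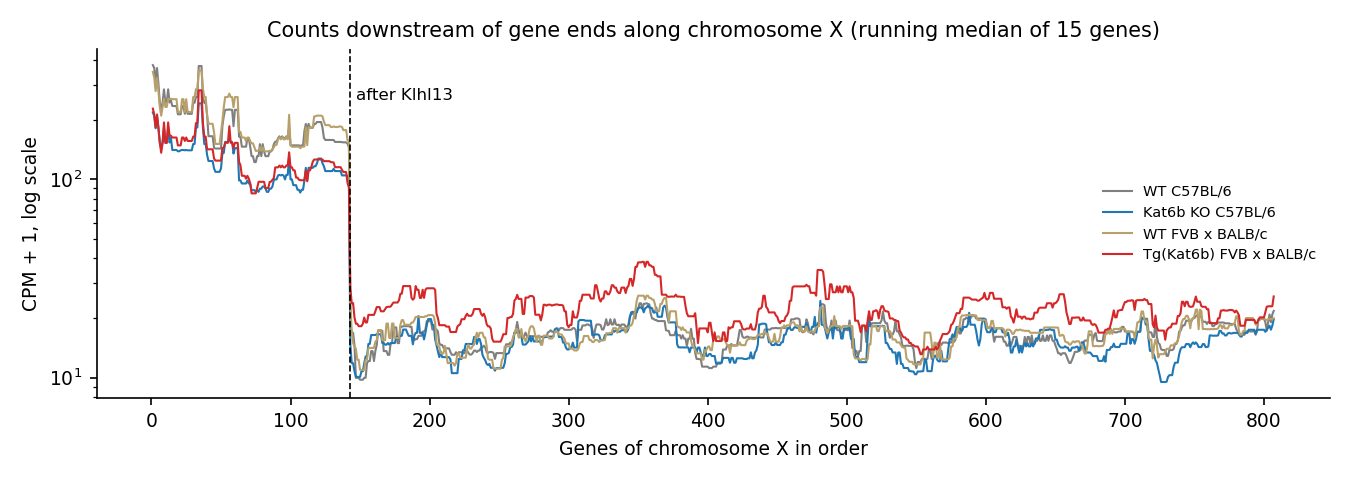
CPM at gene ends along chromosome X in gene order, as a running median over neighbouring genes for each group (log axis), with a dashed line after Klhl13. Counts drop from 1337 at Klhl13 to 94 at the next gene, and the excess before the line is 1.71-fold higher in WT C57BL/6 than in KO and 2.04-fold higher in WT FVB x BALB/c than in Tg.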

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

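Of the tests in this part, the copy-number, fewer-copies and sex tests, the bound for the abundance offsets, which were themselves planned, the thinning to equal depth and the present way of drawing pairs of splits, changed after a first run, were chosen after the result was seen. The counts on proximal X form the first pattern: gene ends through Klhl13 had on average 10.4 times the counts of the rest of X (6.21 to 15.1 in single libraries), and the excess was lower in KO and in Tg than in their WT groups. Per kb, this excess at promoters was 1.14 ± 0.111 times that at gene ends (SD over 16 libraries), an additive amount such as Drosophila spike-in reads placed on a chromosome of the same name would add. In Tg, with enhancer regions on Y near 0, the ends of Uty and Eif2s3y still held 3415 and 1147 counts (sums of 4 libraries) against 3690 and 1086 in WT FVB x BALB/c, whereas Srsy fell from 36 to 3. These sums are not scaled to depth. With mean gene-end totals of 447768 in Tg and 292134 in WT FVB x BALB/c, the ends of Uty and Eif2s3y were lower in Tg relative to depth, but far from absent. A gain of proximal X copies is excluded, because it would multiply the promoter signal and give a quotient of about 1, where 0.238 ± 0.0633 was found; an earlier test on the 90th percentile of promoter counts (2.28 ± 0.417) decided nothing. An effect of Kat6b loss on proximal X chromatin stays open for part of the KO fall, since the strongest proximal promoters changed by -0.33 (SE 0.05 over promoters, which are not independent replicates). Such an effect gives no reason for the excess in WT, nor for the median change of -0.50 at the same promoters in Tg. A candidate explanation is that the proximal X counts are spike-in reads, in which case scaling to them bears on total accessibility per cell, but differences in the ratio of mouse to fly cells could do the same and were not tested.

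Tg library 4 stands apart through its Y counts, 9.01 CPM in enhancer regions (95% interval 5.71 to 13.5) against 0.458 to 0.967 in the other Tg libraries and 54.1 in WT FVB x BALB/c. The Y counts put its WT-like share at 15.5%, the Kat6b promoter at 18.6% and the chromosome 14 enhancer regions at 20.0% and 22.1%. A male transgenic embryo with fewer transgene copies is excluded, since its Y counts were 16.7% of WT where a male would show about all. The deviation of Tg 4 had a slope of 0.0206 (SE 0.00210) on the difference of WT C57BL/6 in autosomal enhancer regions. This slope lay within the -0.0331 to 0.0503 of Tg libraries 1 to 3 and argues against WT C57BL/6 material. At promoters the slope was 0.0528 (SE 0.00401), above the 0.0337 to 0.0478 of Tg libraries 1 to 3, so a small share of such material is not excluded. On the difference of WT FVB x BALB/c the slope was 0.259 (SE 0.00363) in the same enhancer regions and 0.192 at promoters, against at most 0.0752 and 0.0461 in Tg libraries 1 to 3. A candidate explanation is therefore an admixture of WT FVB x BALB/c cells or DNA in this library, and without it 11243 promoters and 5909 enhancer regions passed in Tg.

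The 11470 promoters called in Tg, with falls at weak and rises at strong promoters, form the third pattern. Offsets that follow abundance kept 5500 of these calls, so one smooth trend, such as a difference in enrichment efficiency gives, may be a source of the larger part of them, but it gives no reason for the 5500 kept. This reading rests on a count of calls kept that replaced, after both were seen, a count of all 7219 calls with the offsets, which lay between the bounds and decided nothing. Thinning every library to the smallest total kept 4362, between the bounds set for depth, which cannot be told apart from the genotype here because thinning also lowers power. Sex cannot be told apart either, because 0 of the 2 groups held libraries both with and without Y signal, and an effect of Kat6b gain stays among the open explanations.

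Apart from Tg library 4, 3 libraries lay farther from the rest of their group than the limit of the Dixon gap test allows, at regions named in the text. These were the Trim16 promoter in WT C57BL/6 library 2 (62.6 CPM, others 54.8 to 55.5), the Anxa2 promoter in KO library 1 (39.6, others 35.1 to 35.6), the enhancer region at 100760058 on chromosome 11 in KO library 1 (128, others 106 to 107) and that at 146744513 on chromosome 6 in WT FVB x BALB/c library 2 (82.5, others 84.9 to 85.0). In all 5 of 172 groups exceeded the limit (2.91%), where chance gives about 5%. The effects of loss and gain differed, by the edgeR test of the difference, at 5926 promoters and 4708 enhancer regions. At promoters named in the text the KO change minus the Tg change was -3.65 for Kat6b (edgeR adjusted p = 6.0e-98), 1.26 for Zfp970 (1.7e-20), 1.63 for Isoc2b (3.0e-20), 1.13 for Zfp960 (2.2e-18) and 1.18 for Zfp937 (1.3e-17).

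Other divisions of the same libraries were fitted to see whether chance can be excluded for each count. For the regions called in the comparisons of groups listed next, 1 of 35 splits, the real one, reached the real count. That is the smallest share that 35 splits allow, and it lies under the 5% bound. Splits that mix the groups carry the real difference as spread, which lowers their counts. The result argues against chance alone, but it cannot tell genotype or background from any other difference between the groups, such as sex or handling. The backgrounds were not split at gene ends. At promoters the real and highest other counts were 798 and 25 in KO, 11470 and 690 in Tg, and 3749 and 20 between backgrounds. In enhancer regions they were 3597 and 2, 5847 and 477, and 6288 and 16. At gene ends they were 231 and 3 in KO and 952 and 1 in Tg. The highest other count in Tg, at promoters and in enhancer regions, came from the split that exchanges Tg library 4 and WT FVB x BALB/c library 4. Chance could not be excluded for the number of gene lists, since 2 of 35 splits gave at least the real 2 lists in KO (highest other 4) and 4 of 35 at least the real 8 in Tg (highest other 10). The splits other than the real one that reached these numbers kept 3 libraries of a real group together. They carry part of the real difference and cannot show what chance alone gives. For the difference of effects 4 of 100 drawn pairs of splits, under the 5% bound, reached the real 5926 promoters (highest other 7695). The 3 that exceeded it all kept the real Tg split beside another KO split, and the highest without the real Tg split called 3. The count thus follows the Tg split and cannot show that the KO effect adds to the difference beyond chance. In enhancer regions only the real pair, 1 of 100, reached 4708 (highest other 2781). The correlation of 0.38 between KO and Tg changes at promoters was reached in size by 2 of 100 pairs, the real one included (highest other 0.474). This lies under the 5% bound, but only for the correlation with the trend with abundance left in. The smaller correlation under offsets that follow abundance was not put to this test, so chance stays open for it.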

How the results depend on the processing

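Alternatives chosen after seeing the data were the proximal X scaling, the thinning to equal depth, the abundance (loess) offsets for gene lists, with a fixed or an estimated correlation, and the list without Kat6b. Where no cause is given below, the cause was not tested. At promoters the 798 KO calls became 362 at FDR 0.01, 427 with DESeq2, 371 with gene-end factors (232 higher, 139 lower), 67 after thinning and 16662 with proximal X scaling (16661 higher), and the balance turned to 294 higher and 425 lower with library totals and 269 and 430 with loess offsets. The 11470 Tg calls became 7219 with loess offsets (3619 higher, 3600 lower), 4538 after thinning (2574 and 1964), 11337 with gene-end factors (10047 and 1290) and 15329 with proximal X scaling (15284 and 45). Between backgrounds 3749 became 2288 at FDR 0.01 and 6194 with gene-end factors (421 and 5773), and loess offsets gave 1592 higher and 1740 lower. The 5926 differences of effects became 7599 with gene-end factors (575 and 7024), and split 2482 to 2024 with loess offsets and 1544 to 3201 with DESeq2. In enhancer regions the 3597 KO calls became 1502 after thinning and 13345 with proximal X scaling (13321 and 24), with 2366 higher and 825 lower under gene-end factors. The 5847 Tg calls became 3019 after thinning and 13087 with proximal X scaling (13072 and 15), with 7246 (1670 and 5576) under library totals and 5274 and 779 under gene-end factors. Those factors split the differences of effects 1202 to 2973 and the backgrounds 1699 to 4915, and library totals split the former 3766 to 1313. At gene ends the 231 KO calls became 117 on autosomes alone, 88 after thinning and 6405 with proximal X scaling (6401 and 4), with 77 and 188 under library totals and 79 and 172 under promoter factors. The 952 Tg calls became 3040 with library totals (273 and 2767), 2934 with promoter factors (276 and 2658), 585 with loess offsets (287 and 298), 549 after thinning and 4482 with proximal X scaling (4474 and 8). The 2 gene lists in KO became 0 with estimated correlations, and loess offsets kept neither and gave 1 other, HOX (median 0.15, camera adjusted p = 0.00807), as they did with an estimated correlation. The 8 lists in Tg became 5 with estimated correlations, 5 with loess offsets (4 of the 8 and the cell cycle list, which turned lower), 4 with both, 17 with fry and 13 with gene-end factors. The correlation of 0.38 became 0.125 with loess offsets, and the enhancer ratio in Tg was 0.25 from median log2 CPM (exact p = 0.0857). With 1 library left out, promoter calls ranged over 537 to 739 in KO, 10165 to 11243 in Tg, 2988 to 3535 between backgrounds and 5311 to 6229 for the difference, enhancer calls over 3071 to 3251, 5089 to 5909, 5782 to 6055 and 4295 to 4791, and gene-end calls over 139 (without WT C57BL/6 4) to 230 in KO and 783 to 932 in Tg. Lists ranged over 1 (without WT C57BL/6 1) to 2 in KO and 8 to 9 in Tg. The promoter ratio was 0.0510 to 0.12 in KO (0.12, exact p = 0.0286, without WT C57BL/6 2) and 0.37 to 0.47 in Tg (exact p = 0.0571 without Tg 1, 2 or 3), and the enhancer ratio 0.0525 to 0.11 (0.11, exact p = 0.0286, without WT C57BL/6 2) and 0.13 to 0.19 (exact p = 0.0571 without any 1 Tg library, the smallest p such a test can give being 0.0286). With a replicate block, promoter calls were 763, 11523, 5951 and 3797 for KO, Tg, the difference and backgrounds, enhancer calls 3615, 5866, 4773 and 6321, gene-end calls 217 in KO and 939 in Tg, and the Tg ratios of 0.41 and 0.15 had p = 0.125 in the exact test within blocks, the smallest it can give. The numbers did not pair libraries: correlations of 24 pairs lay between -0.11 and 0.06, and 2 of 24 matched best with their own number. With proximal X scaling, which raises every change alike, log2 changes below 0 at named regions, called or not, turned positive in KO at Kcna6 0.0206, Akr1e1 0.0768, Garnl3 0.13, Cdh5 0.15, Baiap2l1 0.18, Anxa2 0.18, Cadm3 0.19, Gata1 0.20, Ache 0.23, Nkain4 0.23, Prrx1 0.23, Id1 0.23, Cdkn1a 0.32, Syt1 0.32, Dlx5 0.33, Tubb3 0.36, Gusb 0.39, Elavl3 0.44, Tek 0.51, Slc1a2 0.52, Ing4 0.68 and at chromosome 14 regions 22308414 and 22321389 (0.45 and 0.60), and in Tg at Acta2 0.0664, Hoxb2 0.12, Flt1 0.15, Tbr1 0.18, Hoxa9 0.21, Fcer1g 0.22, Pcdhb10 0.23, Zfp42 0.26, Tek 0.28, Pcdhb11 0.29, Aldh1l1 0.29, Hba-a2 0.31, Dnmt3l 0.33, Hoxc10 0.35, Emcn 0.38, Hoxa10 0.38, Itgam 0.43, Tbx18 0.44, Csf1r 0.44, Gata1 0.46, Elavl4 0.47, P2ry12 0.50, Pcdhac2 0.54, Erg 0.61, Cdk6 0.67, Mcm3 0.75, Dazl 0.75. Gene-end factors turned Erg 0.0233, Cdk6 0.10, Mcm3 0.17, Dazl 0.18 in Tg, thinning turned Emcn 0.0491, and loess offsets turned Brpf1 -0.13 and Itgam 0.0191 and the HOX (-0.0410), protocadherin (0.0398) and cell cycle (-0.12) lists. Of the other changes at named regions 124 were weaker and 55 stronger in KO, and 108 and 6 in Tg; of those of lists 7 and 2 in KO, and 8 and 15 in Tg. A difference test from only the groups of the comparison was not run. Thinning lowers power and also evens out depth between groups, so the calls it removed cannot be put down to either alone. At gene ends it left 5916 testable regions of 15186.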

Other observations

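Gene families read from symbols add to the fixed lists. Among 152 families with at least 15 tested promoters, the olfactory receptors (Olfr) had 787 of 1107 promoters lower in Tg (median log2 change -0.83) and the vomeronasal receptors (Vmn) 200 of 311 (-0.84), sensory receptor genes that are silent in most tissues. In KO 14 and 6 of them fell (medians -0.28 and -0.24). Both families are among the least accessible promoters, and with offsets that follow abundance 83 olfactory receptors fell and 12 rose in Tg (median -0.17, limma camera adjusted p = 0.350, and 0.0410 with an estimated correlation). No family passed with single factors and an estimated correlation, in KO or in Tg. With the abundance offsets 4 families passed in Tg. The zinc finger genes (Zfp), many of which lie in clusters and silence transposable elements, had 175 of 392 promoters lower and 49 higher (median -0.18, camera adjusted p = 2.0e-10, and 0.0410 with an estimated correlation). The X-linked reproductive homeobox genes (Rhox) had 29 of 31 higher (median 0.94, 7.8e-08, and 0.00555 with an estimated correlation) in libraries that also lacked the Y signal of WT. On X outside its proximal part, gene ends also rose in Tg (median 0.56), though promoters had a median of 0.06, both with TMM factors. The Rhox rise therefore cannot be told apart from a difference in sex. Histone demethylase genes (Kdm) had 9 of 17 higher and 0 lower (median 0.18, 0.00169, and 0.276 with an estimated correlation), and the SOX family 9 of 19 higher and 2 lower (0.00452, and 0.193 with an estimated correlation). In KO the offsets left 1 family, Btbd, lower, with 9 of its 10 falls on the proximal X, where all promoters may hold spike-in reads (promoter to gene-end excess 1.14; 10 of 33 lower, median -0.22, adjusted p = 6.1e-08, and 0.176 with an estimated correlation). Members of these families share sequence, so counts can belong to a paralog.

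Neighbouring regions of at least median abundance changed together in every comparison, most in Tg. Less abundant regions were left out, so adjacent means next to each other among those kept. After the trend with abundance was removed, the correlation of the Tg change between adjacent autosomal regions at least 10 kb apart was 0.625 at promoters, 0.325 in enhancer regions and 0.203 at gene ends, while it was 0.176, 0.0567 and 0.0654 in KO and 0.276, 0.107 and 0.116 between the WT backgrounds, all above the highest of 100 shuffled orders. These are correlations across regions, which are not independent replicates.

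Of the tests below, those of the order of regions and of the shared WT libraries were chosen after the result was seen. A chance order of regions is excluded for the Tg pattern in enhancer regions, since the highest of 100 shuffled orders gave 0.0264 against 0.325. A hypothesis is that the Tg change follows the gene density of its surroundings. Across gene ends it correlated with the number of genes within 1 Mb (Spearman rho = 0.221), from a median of -0.14 in the least dense of 4 groups to 0.07 in the densest, but with rho = 0.138 after removal of the trend with abundance. At promoters rho was 0.0407, and 0.249 after that removal. The first value met the bound set for the hypothesis, and the others lay on both sides of it, so it stays open.

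A further hypothesis concerns the KO changes in enhancer regions, which went with the difference between the WT backgrounds. Of 2058 rises in KO, 1071 were also higher and 239 lower in WT FVB x BALB/c than in WT C57BL/6 (371 and 400 from independent lists), and of 1539 falls 945 were also lower and 60 higher (299 and 277). The other classes had an excess too. At promoters 98 were higher and 130 lower in both (29.2 and 44.7 from independent lists), and at gene ends 28 and 26 (1.18 and 2.81). Across autosomal enhancer regions the 2 differences correlated with r = 0.49, and their covariance was 0.0762 where 20 simulations of unchanged groups sharing the WT C57BL/6 libraries gave 0.0161 (r = 0.51). With these libraries divided between the comparisons r was 0.333 (0.293 to 0.369 over 6 divisions) in enhancer regions, which argues against chance deviations of single shared libraries as the whole cause, but -0.0892 at promoters and 0.0334 at gene ends. Changes of at least 2-fold lay on all 19 autosomes, which also argues against a few residual donor-strain segments in the knockout line as the whole cause. Only 3 pairs of adjacent enhancer regions both changed that much (highest of 100 shuffled orders 5), but with 166 such regions in all this count has little power. What stays open is that the WT C57BL/6 cultures as a group may differ from the others in cell state, handling or widely spread alleles, so that part of the 3597 KO calls in enhancer regions would not be due to Kat6b. A second set of WT C57BL/6 cultures prepared with the KO would test this.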
